A study of Homo sapiens with 24 samples.

How the data were processed

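RNA sequencing had been done on total RNA of the cell lines SH-SY5Y and SK-N-BE(2), grown in minimum essential medium. The cells carried lentiviral constructs, a short hairpin RNA against NDUFS6 or its coding sequence, or the matching empty vector, after puromycin selection. Per the labels and the submitters' processing notes, RNA was extracted with TRIzol, strand-specific TruSeq libraries were read on an Illumina NovaSeq sequencer, and FastQC 0.11.2, STAR (version not given) and StringTie 1.3.1c were run with the hg38 build. The counting settings, the annotation release and the number of reads per library are not given in the sources used here. The deposited table held FPKM values per gene, which the authors made, in 60564 rows and 24 libraries. With no counts, the depth per library is unknown, and the spread between the 3 libraries of a group is the only measure of precision. The SD of the log2 difference between libraries of a group lay between 0.190 and 0.323. Gene types, positions and exons came from GENCODE release 29, in which 58457 of the rows and 15787 of the 15903 tested genes (99.3%) had a record. Of the rows, 2796 had no symbol, 179 of them tested, and 1827 had a symbol carried by several rows, which were kept apart by gene identifier.

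The analysis used R 4.3.3 with limma 3.58.1 and data.table (1.17.8). Genes with at least 1 FPKM in at least 3 libraries were tested. Values were taken as log2(FPKM + 1), and limma fitted all 24 libraries in 1 model with 8 groups (16 residual degrees of freedom), with a mean-variance trend and robust moderation. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. Each construct was compared with its own empty vector control in each line, and the difference between the lines was tested as an interaction. Genes called the same way in both lines, and genes called oppositely by knockdown and overexpression of a line, were counted from these calls, and NDUFS6 was left out of every count. The counts expected for independent lists are the products of the list sizes over the tested genes. Among genes called in both comparisons, agreement in direction was tested with Fisher's exact test, two-sided. Whether more genes were called in both than independent lists give was not tested. The empty vector controls of each line were compared with each other in the same model.

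The comparisons, tests, named-gene rule, 36 gene lists and all but 3 alternatives were set before the data were examined. The lists were nuclear complex I subunits, complex I assembly factors, mitochondrially encoded OXPHOS subunits, nuclear complex II to V subunits, mitochondrial ribosomal proteins, cytosolic ribosomal proteins, glycolysis and glucose uptake, tricarboxylic acid cycle, ATF4 and integrated stress response, mitochondrial protein folding stress, endoplasmic reticulum unfolded protein response, hypoxia response, NRF2 and antioxidant defence, cell cycle genes of G1/S and S phase, cell cycle genes of G2/M, MYC and MYCN target genes, p53 target genes, apoptosis regulators, adrenergic neuroblastoma identity, mesenchymal neuroblastoma identity, extracellular matrix and adhesion, neuronal differentiation, type I interferon response, inflammatory and NF-kappaB targets, cholesterol synthesis, fatty acid synthesis and oxidation, ferroptosis regulators, mitophagy and autophagy, immediate early genes, heat shock proteins, Schwann cell markers, fibroblast and stroma markers, immune cell markers, epithelial cell markers, endothelial cell markers and replication-dependent histones. Of the members, 900 were found by the symbol in the table and 46 by gene identifier under a current symbol. The 33 lists with at least 5 tested members were tested with camera, which compares the members of a list with all other genes, with a preset correlation of 0.01 between members and again with the correlation estimated from the data, each adjusted over the lists. The immune, epithelial and endothelial lists had 1, 3 and 2 tested members and were not tested, so single markers are given for them. Lists share members, as do the hypoxia list with glycolysis and the ferroptosis list with the ATF4 and NRF2 lists. The named genes were NDUFS6, the 8 largest rises and 8 largest falls of each comparison among called genes with a symbol, a mean of at least 1 FPKM in the higher group and no overlap between groups, up to 4 members per called list by smallest adjusted p, of which some are given, 6 per direction for genes shared or opposite between comparisons, 6 per test between lines, 4 per direction between controls, and MYCN, CDKN1A, DDIT3, ATF4 and the 3 highest markers of other cells throughout. Some of these genes are not reported here. Genes that share exons with another gene on the same strand, close paralogs and small RNAs are named as uncertain.

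Alternatives were a pseudocount of 0.1, no filter on low values (43264 genes), a mean of at least 5 FPKM (7219 genes), scaling to a fixed sum (TPM) or by median of ratios, only the libraries of the groups compared, the replicate number as a block, limma's library weights, a 2-fold threshold, an estimated correlation, and leaving out each library in turn. Alternatives added once the values had been seen were the other empty vector control of the line, removal of each library's lowess trend of log2 level on gene length (span 0.3), and protein-coding genes without shared exons (10230 genes). Group labels were also permuted over all 10 splits of 3 against 3 libraries and over 100 drawn splits for pairs of comparisons. With 3 libraries per group no outlier test was run.

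The method was tested on simulated data of 15903 genes built on the spread of the libraries, with 50 genes changed at each fold. Of these it recovered 27, 29, 29 and 28 at 1.25-fold in the 4 comparisons, 46, 44, 46 and 43 at 1.5-fold, 48, 49, 48 and 48 at 2-fold and 50, 49, 50 and 50 at 4-fold, 4.17 to 6.36% of the calls fell on unchanged genes, and 0 of the other lists were called beside the raised one, while relabelled splits of the real libraries called up to 21 lists. Genes of the Y chromosome and XIST were left out of named genes and figures. Protein levels, metabolism, cell growth and the reads themselves were not analysed here. A difference that was not called is not shown to be absent.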

Results

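RNA sequencing measured transcript levels in the human neuroblastoma cell lines SK-N-BE(2), which carries an amplified MYCN gene, and SH-SY5Y, which does not. The target, NDUFS6, encodes an accessory subunit of complex I, the NADH dehydrogenase of the mitochondrial respiratory chain. Each line was made to lose NDUFS6 with a lentiviral short hairpin RNA (knockdown) or to gain it with its full-length coding sequence (overexpression), and each construct had its own empty vector control. The 24 libraries formed 8 groups of 3, all of 1 batch in the labels. The labels call the 3 libraries of a group biological replicates. Whether they came from separate infections is not given in the sources used here, so p-values measure the spread between these libraries, which may be technical. The values were FPKM (fragments scaled to transcript length and to the mapped fragments of the library), and the number of reads behind them is unknown. FPKM summed to between 249708 and 276091 per library, and between 12607 and 14018 genes reached 1 FPKM. Principal component 1, with 56.4% of the variance, separated the lines. Log2 changes are on the log2(FPKM + 1) scale, which understates the change of low genes, and ± gives the SD of the 3 libraries of a group (n = 3). For the genes and lists called in a comparison, values against a line's other empty vector control, or with 1 library left out, are given where the call was lost or the value moved more than 1.5-fold, and were still called where nothing else is said. AC022336.2, AC093010.3, AC136621.1, CD68, CENPA, COL3A1, DDIT3, ELAVL3, H19, HOXD10, MIR4442, PP7080, RPL23A, RPL36A-HNRNPH2, SLC6A2, SLIT1, STON1, TOMM6 and ZBED6 share exon sequence with another gene on the same strand, so their values are uncertain.

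NDUFS6 itself (ENSG00000145494, chromosome 5, 1801400 to 1816605 in hg38) followed the labels in all 4 comparisons. In SK-N-BE(2) it stood at 1.09, 1.61 and 1.3 FPKM in the knockdown libraries and at 9.29, 12.2 and 11.9 in their controls, an 8.36-fold lower mean (1.33 ± 0.261 against 11.2 ± 1.63, log2 change -2.38, SE 0.118, limma adjusted p = 1.35e-12). In SH-SY5Y the knockdown libraries held 3.11, 3.98 and 4.98 FPKM and their controls 11.2, 11.1 and 12.1, a 2.85-fold lower mean (4.02 ± 0.939 against 11.5 ± 0.566, log2 change -1.33, SE 0.118, limma adjusted p = 7.29e-09). Overexpression in SH-SY5Y gave 214, 211 and 199 FPKM against 10.2, 11.5 and 11.2, a 19.0-fold higher mean (208 ± 7.74 against 11 ± 0.679, log2 change 4.13, SE 0.118, limma adjusted p = 1.11e-14). In SK-N-BE(2) the overexpression libraries held only 14.9, 17.8 and 19.0 FPKM against 11.8, 13.9 and 12.7, 1.34-fold more (17.2 ± 2.07 against 12.8 ± 1.03, log2 change 0.39, SE 0.118, limma adjusted p = 0.017). That rise was not called without overexpression replicate 2 or 3 or control 1 or 3 (log2 changes 0.37, 0.33, 0.34 and 0.39, limma adjusted p from 0.0505 to 0.0834), and it was 0.59 against the line's other empty vector control (limma adjusted p = 0.000567). It also missed the threshold with no filter on low values and with only the compared groups in the fit (limma adjusted p = 0.0511 in both). The difference between the lines was -1.05 for knockdown (limma adjusted p = 2.11e-05) and -3.73 for overexpression (limma adjusted p = 1.24e-11), both as SK-N-BE(2) minus SH-SY5Y. Between the empty vector controls of a line NDUFS6 differed by -0.19 in SK-N-BE(2) (limma adjusted p = 0.229) and by 0.06 in SH-SY5Y (limma adjusted p = 0.745).

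**Figure D1:**
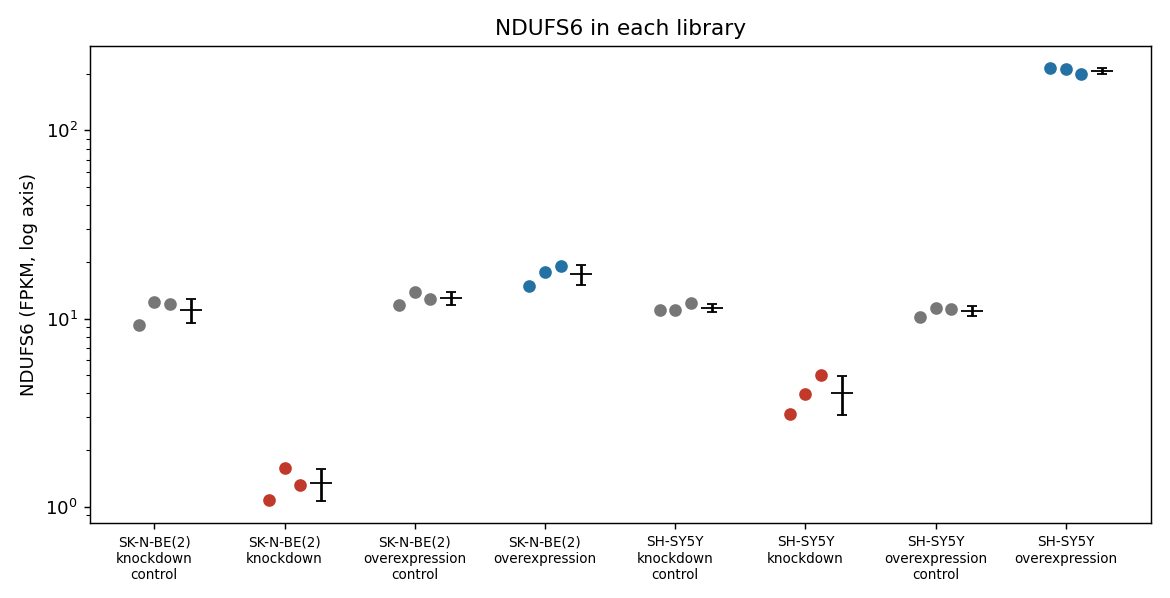
NDUFS6 level in FPKM on a log axis in the 8 groups, with points for the single libraries and bars for the mean ± SD of 3 libraries. The knockdown libraries average 1.33 FPKM in SK-N-BE(2) and 4.02 in SH-SY5Y, and the overexpression libraries 17.2 and 208.

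Knockdown in SK-N-BE(2) asked which transcripts changed when this MYCN-amplified line lost most of its NDUFS6 RNA. Genes of the unfolded protein response and the integrated stress response were among the largest rises. HMOX1, the heme-degrading oxygenase, went from 1.01 ± 0.264 to 204 ± 66.1 FPKM (log2 change 6.63, SE 0.162, limma adjusted p = 5.05e-17). DDIT3, which encodes the stress transcription factor CHOP, went from 3.33 ± 0.478 to 273 ± 15.8 FPKM (log2 change 5.99, SE 0.138), and HSPA5, the endoplasmic reticulum chaperone BiP, from 64.2 ± 0.865 to 928 ± 86.1 (log2 change 3.83, SE 0.0494). The other leading rises were in ATF3, FOSL1, CHAC1, SLC7A11, HERPUD1 and IGFBP3, with log2 changes of 4.81, 4.02, 4.29, 4.11, 4.04 and 4.21 (limma adjusted p from 2.72e-21 to 1.03e-14 with DDIT3 and HSPA5). The leading falls were -4.64 for NT5E, -2.74 for GJA1, -2.49 for MT-TW, -2.46 for INSM2, -2.34 for BCHE, -2.34 for ITM2A, -2.31 for SLFN11 and -2.30 for TMEM100 (limma adjusted p from 5.85e-17 to 2.99e-13). MT-TW is a mitochondrial transfer RNA, too short to be measured with certainty in such libraries. Against the line's other empty vector control, log2 changes were 0.82 for IGFBP3, -1.75 for NT5E, -1.67 for GJA1, -0.61 for MT-TW, -1.14 for SLFN11 and -1.39 for TMEM100. Against that control BCHE (-0.06) and ITM2A (-0.13) were not called.

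Of the endoplasmic reticulum unfolded protein response list, 20 of 20 rose and 0 fell (median 2.38, camera adjusted p = 2.43e-20), with XBP1, a transcription factor of that response, and DNAJB9, a chaperone, at 2.45 and 3.12. Of the ATF4 and integrated stress response list, 34 of 35 rose and 1 fell (median 1.8, camera adjusted p = 8.1e-25), including the amino acid transporter subunits SLC7A5 and SLC3A2 at 2.32 and 2.40, and ATF4 itself went from 81.2 ± 4.18 to 211 ± 14.8 FPKM (1.37, limma adjusted p = 2.03e-12). Among immediate early genes 20 of 21 rose and 0 fell (median 1.5, camera adjusted p = 4.83e-15), with the transcription factors JUN and EGR3 at 2.32 and 2.15, and among heat shock proteins 11 of 14 rose and 0 fell (median 0.63, camera adjusted p = 3.78e-07), with DNAJB1 at 1.73. Of the ferroptosis regulators, which include HMOX1, CHAC1 and SLC7A11, 15 of 19 rose and 2 fell (median 0.42, camera adjusted p = 8.56e-07). In the hypoxia list 18 of 23 rose and 1 fell (median 0.43, camera adjusted p = 1.38e-05), with the growth factor VEGFA and the collagen hydroxylase P4HA2 at 1.41 and 1.36.

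Cell cycle genes of G2/M fell together: 0 of 37 rose and 37 fell (median -0.74, camera adjusted p = 3.84e-20), with the kinase CDK1 and the cyclin CCNA2 at -1.0 and -0.98. MYCN went from 1102 ± 1.79 to 522 ± 88.7 FPKM (-1.09, limma adjusted p = 1.33e-07), and CDKN1A, which encodes the cell cycle inhibitor p21, from 1.03 ± 0.415 to 13.5 ± 2.66 (2.84, limma adjusted p = 4.57e-13). Of the neuronal differentiation list 19 of 32 rose and 6 fell (median 0.36, camera adjusted p = 0.00166), with the neuropeptide NPY and the receptor RET at 3.85 and 1.53. Of the type I interferon list 14 of 23 rose and 1 fell (median 0.35, camera adjusted p = 0.00166), with the proteasome subunit PSMB8 and the sensor OAS3 at 0.63 and -0.91. That list was not called with a mean of at least 5 FPKM (camera adjusted p = 0.0759) or with only the groups compared (camera adjusted p = 0.0885). Calls that rested on the preset correlation were those of p53 targets (17 of 27 rose, 6 fell, median 0.39), NRF2 genes (13 of 26 rose, 7 fell, 0.26), mitophagy (15 of 21 rose, 1 fell, 0.34), extracellular matrix (19 of 36 rose, 7 fell, 0.22), mesenchymal identity (15 of 25 rose, 6 fell, 0.53), apoptosis regulators (14 of 26 rose, 4 fell, 0.21) and adrenergic identity (7 of 25 rose, 13 fell, -0.30), with camera adjusted p from 7.84e-05 to 0.0235 and adjusted p of 0.0888, 0.253, 0.13, 0.147, 0.157, 0.0938 and 0.657 with an estimated correlation. With the other control, values were -0.38 for CDK1, -0.35 for CCNA2 and 0.27 for RET. There OAS3 (0.24) reversed. List medians against it were -0.32 for G2/M genes, 0.20 for mitophagy and -0.59 for adrenergic identity. It ended the list calls of neuronal differentiation (0.07), mesenchymal identity (0.16) and apoptosis regulators (0.11).

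Many respiratory chain genes fell. Of the nuclear complex I subunits other than NDUFS6, 0 of 36 rose and 17 fell (median -0.19, camera adjusted p = 0.00862, adjusted p = 0.657 with an estimated correlation), with NDUFS5 and NDUFB3 at -0.99 and -0.65. Of the nuclear subunits of complexes II to V, 0 of 38 rose and 21 fell (median -0.20, camera adjusted p = 0.00327, adjusted p = 0.657 with an estimated correlation). Of the subunits encoded by mitochondrial DNA, 0 of 13 rose and 12 fell (median -0.49, camera adjusted p = 4.28e-05, adjusted p = 0.0938 with an estimated correlation), with MT-CYB and MT-ND2 at -0.62 and -0.35. Mitochondrially encoded genes held 27.8 ± 0.399% of the FPKM after knockdown and 33.8 ± 0.223% in its controls. Complex I assembly factors (4 of 16 rose, 4 fell, camera adjusted p = 0.935), the tricarboxylic acid cycle (6 of 21 rose, 9 fell, camera adjusted p = 0.592) and replication-dependent histones (0 of 6 rose, 2 fell, camera adjusted p = 0.776) were not called here or in any other comparison. Adjusted over the list alone, the counts were 18 and 2 for hypoxia genes, 14 and 7 for NRF2 genes, 18 and 6 for p53 targets, 7 and 14 for adrenergic identity, 16 and 6 for mesenchymal identity, 21 and 8 for extracellular matrix, 17 and 2 for ferroptosis regulators, 17 and 1 for mitophagy and 12 and 0 for heat shock proteins, and unchanged elsewhere. Markers of other cells gave log2 changes of -0.27 for PMP22 and -1.15 for GFRA3 (Schwann cells), -0.17 for LUM and -0.07 for FBLN1 (stroma), 0.25 for CD68 (immune), 0.42 for EPCAM and 0.22 for CLDN4 (epithelium) and 0.29 for EGFL7 and -0.58 for EMCN (endothelium), and PMP22, GFRA3, CD68, EPCAM and EMCN passed the test (limma adjusted p from 5.76e-08 to 0.0324). The other control left MT-ND2 (-0.04), GFRA3 (-0.02), CD68 (0.20), MT-CYB (0.03), EPCAM (-0.16) and EMCN (0.03) uncalled. Against it PMP22 (0.19) turned round. The medians of lists there were -0.12 for complexes II to V. List calls lost there were mitochondrially encoded subunits (-0.09). LUM (-0.26) and FBLN1 (-0.13) were called without replicate 2. CD68 (0.26, 0.18, 0.25, 0.25 and 0.25) was not called without replicates 2 and 3 and controls 1, 2 and 3. EPCAM (0.29) was not called without replicate 2. CLDN4 (0.28) was called without replicate 1.

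Over all genes, limma called 8854 of the 15902 tested genes other than NDUFS6 (55.7%), 4361 higher and 4493 lower, and 724 of them by at least 2-fold (507 higher, 217 lower). Of those 724, 365 (50.4%) were also at least 2-fold changed in the same direction against the line's other empty vector control, and 665 (91.9%) were called in that direction at any size. Higher genes made up 49.2% of the calls and 60.8% under TPM scaling. In this and all other comparisons, the lists whose median, mean and test differed in sign were not called.

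**Figure D2:**
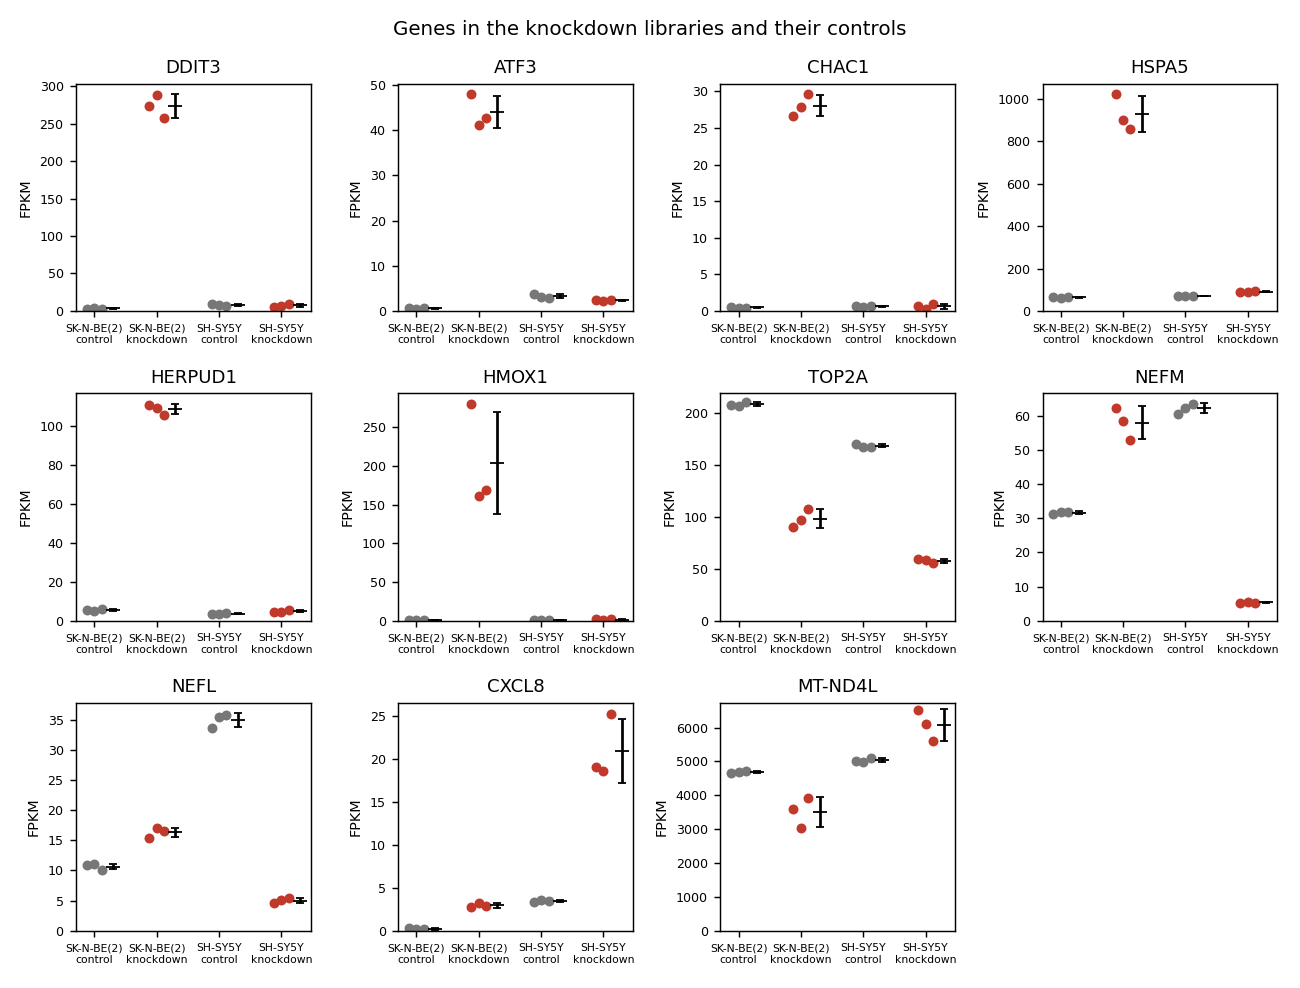
FPKM from 0 of 11 genes in the knockdown and control libraries of both lines, with points for libraries and bars for the mean ± SD of 3. DDIT3 averages 273 FPKM in SK-N-BE(2) knockdown and 3.33 in its controls, and NEFM 5.39 in SH-SY5Y knockdown and 62.1 in its controls.

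In SH-SY5Y knockdown, neuronal genes were lower and matrix and inflammatory ones higher. Overexpression in this line moved neuronal and NF-kappaB lists the same way against its control, so dependence on NDUFS6 is not shown. NEFM, a neurofilament protein, fell from 62.1 ± 1.46 to 5.39 ± 0.135 FPKM (log2 change -3.30, SE 0.0498, limma adjusted p = 1.31e-20). MAB21L2 rose from 0.134 ± 0.0782 to 24.4 ± 2.54 FPKM (log2 change 4.48, SE 0.0571, limma adjusted p = 7.44e-22). Other leading rises were 4.04 for LRRC17, 3.65 for HTR2B, 3.63 for IGFBP3, 3.61 for C7, 3.34 for KCTD12 and 3.30 for AC114284.1 (limma adjusted p from 7.44e-22 to 5.38e-14). The other leading falls were -3.41 for H19, -3.38 for ARHGAP36, -3.09 for SLIT1, -3.04 for ELAVL3, -3.02 for HOXD10, -3.01 for VIP and -2.99 for NPTX2 (limma adjusted p from 7.44e-22 to 1.25e-14). The other control gave -1.92 for VIP.

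Of the neuronal differentiation list 2 of 32 rose and 25 fell (median -1.39, camera adjusted p = 1.81e-11), with the neurofilament NEFL and the secretory granule gene SCG3 at -2.59 and -2.73. In the mesenchymal identity list 14 of 25 rose and 5 fell (median 0.36, camera adjusted p = 0.00155, adjusted p = 0.0687 with an estimated correlation), with vimentin (VIM) and the co-activator YAP1 at 2.20 and 1.54. Of the extracellular matrix genes 26 of 36 rose and 5 fell (median 0.51, camera adjusted p = 3.77e-08), with the matrix protease MMP14 and the cadherin CDH2 at 2.26 and 1.55. Fibroblast and stroma markers, some of them in the matrix list too, moved with them: 10 of 12 rose and 1 fell (median 0.62, camera adjusted p = 8.79e-05), with the proteoglycans DCN and LUM at 3.07 and 2.38. CD68, a macrophage marker, rose from 1.89 ± 0.371 to 10.1 ± 1.5 FPKM (1.94, limma adjusted p = 7.27e-13). Of the inflammatory and NF-kappaB targets 12 of 13 rose and 0 fell (median 1.15, camera adjusted p = 4.21e-09), with the chemokines CXCL8 and CXCL1 at 2.28 and 1.73. In the type I interferon list 17 of 23 rose and 2 fell (median 0.56, camera adjusted p = 2.31e-05), with IFIT3 and IFI44 at 1.10 and 1.6. Against the other control, changes were 3.57 for VIM, 2.61 for YAP1 and 3.36 for CD68. List medians there were 1.65 for mesenchymal identity, 1.38 for extracellular matrix, 1.45 for stroma markers, 1.73 for NF-kappaB targets and 0.97 for type I interferon response.

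Cell cycle genes fell. In G2/M 0 of 37 rose and 37 fell (median -1.05, camera adjusted p = 5.35e-22), with the kinases TTK and CDK1 at -1.51 and -1.03. In G1/S and S phase 0 of 31 rose and 23 fell (median -0.44, camera adjusted p = 4.08e-06, adjusted p = 0.228 with an estimated correlation), with the replication factor CDC45 at -0.80. MYCN, at 2.00 ± 0.286 FPKM in the controls, stood at 1.29 ± 0.5 (-0.41, limma adjusted p = 0.00553), and CDKN1A went from 47.8 ± 2.84 to 75.6 ± 9.45 (0.64, limma adjusted p = 0.000299). For glycolysis and glucose uptake 2 of 23 rose and 19 fell (median -0.54, camera adjusted p = 1.68e-06, adjusted p = 0.101 with an estimated correlation), and for the hypoxia list, which shares 8 members with other lists, 3 of 23 rose and 18 fell (median -0.70, camera adjusted p = 4.08e-06). The kinase PDK1 was at -1.31 and the hexokinase HK2 at -1.75. For fatty acid synthesis and oxidation 4 of 23 rose and 14 fell (median -0.24, camera adjusted p = 0.0204, and 0.0596 with a mean of at least 5 FPKM), with the desaturase SCD at -1.49, and for cholesterol synthesis 2 of 21 rose and 17 fell (median -0.36, camera adjusted p = 0.000272, adjusted p = 0.0509 with an estimated correlation). Log2 changes against the other control were -0.79 for MYCN, 2.33 for CDKN1A and -0.90 for HK2. List medians against it were -0.79 for G1/S and S phase genes. It ended the calls of hypoxia genes (-0.31), fatty acid genes (-0.16) and cholesterol synthesis (-0.17). MYCN (-0.27) was not called without replicate 3.

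Mitochondrially encoded subunits rose: 12 of 13 rose and 0 fell (median 0.55, camera adjusted p = 9.86e-07), with MT-CYB and MT-ND2 at 1.20 and 0.76. Mitochondrially encoded genes held 37.0 ± 0.967% of the FPKM after knockdown and 31.1 ± 0.305% in its controls. Of the apoptosis regulators 16 of 26 rose and 6 fell (median 0.33, camera adjusted p = 0.00858), with BCL2, an inhibitor of apoptosis, at 1.36. Calls lost with an estimated correlation were complexes II to V (1 of 38 rose, 18 fell, median -0.16), endoplasmic reticulum stress (16 of 20 rose, 1 fell, 0.36) and ferroptosis regulators (10 of 19 rose, 3 fell, 0.28), with camera adjusted p from 0.000265 to 0.0204 and adjusted p of 0.813, 0.355 and 0.142 with an estimated correlation. ATF4 went from 30.7 ± 0.338 to 43.7 ± 2.12 FPKM (0.50, limma adjusted p = 4.19e-06). DDIT3 was at 7.41 ± 2.32 against 7.91 ± 1.25 FPKM (-0.11, limma adjusted p = 0.527) and was 0.97 against the other control (limma adjusted p = 4.34e-06). Adjusted over the list alone, the counts were 1 and 17 for complexes II to V, 4 and 18 for hypoxia genes and 17 and 6 for apoptosis regulators, and unchanged elsewhere. Other markers gave 0.46 for PMP22, -0.21 for GFRA3, -0.41 for FBLN1, -0.03 for EPCAM, -0.09 for CLDN4 and -0.73 for EGFL7, of which PMP22, FBLN1 and EGFL7 passed the test (limma adjusted p from 3.48e-07 to 0.000961), and EMCN was listed at 0 in the controls. Against the other control, log2 changes were 0.39 for MT-ND2, 0.33 for ATF4 and 0.99 for PMP22. EGFL7 (-0.30) was not called there. List medians there were 0.21 for apoptosis regulators, -0.26 for complexes II to V and 0.49 for ferroptosis regulators. DDIT3 (-0.32) was called without replicate 3. Without knockdown replicate 1 the call was lost for complexes II to V (-0.14).

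limma called 8899 genes (56.0%), 4186 higher and 4713 lower, and 1045 of them by at least 2-fold (411 higher, 634 lower). Of those 1045, 832 (79.6%) were also at least 2-fold changed in the same direction against the other control. 1015 (97.1%) were called in that direction at any size. Higher genes made up 47.0% of the calls and 35.4% under TPM scaling. The median log2 change of all genes was -0.105 under TPM scaling.

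Some genes moved the same way in both knockdowns. IGFBP3, the matrix protein gene MGP, the transcription regulator ID1, the secreted protein gene RELN, CXCL8 and the antiviral membrane protein IFITM3 rose in both, with log2 changes in SK-N-BE(2) of 4.21, 2.58, 2.65, 1.81, 1.70 and 1.69 and in SH-SY5Y of 3.63, 2.14, 1.88, 2.30, 2.28 and 1.88. MKI67, the proliferation marker Ki-67, CENPA, the centromere histone, and the paralogs FAM72A, FAM72B, FAM72C and FAM72D, whose reads cannot be told apart with certainty, fell in both, at -1.8, -1.6, -1.54, -1.53, -1.6 and -1.57 and -1.49, -1.59, -1.71, -1.79, -1.78 and -1.86. All 37 tested genes of G2/M fell in either line. In SK-N-BE(2) the other control gave a smaller rise for IGFBP3. It gave 0.48 for MGP, 1.03 for RELN, -1.15 for MKI67 and -0.81 for CENPA. For FAM72A to FAM72D it gave -0.71, -0.67, -0.82 and -0.75. In SH-SY5Y it gave 3.15 for IFITM3, -1.05 for FAM72A, -1.18 for FAM72B, -1.11 for FAM72C and -1.24 for FAM72D. CXCL8 and IGFBP3 also rose in SH-SY5Y overexpression. 3263 genes were called the same way in both lines (1585 higher and 1678 lower), where independent lists of those sizes would share 1148 and 1332. Another 2250 were called in opposite directions, against 2475 for independent lists, so that 59.2% of the genes called in both lines matched (Fisher's exact test p = 5.71e-43, two-sided, over genes, which are not independent). Across genes the log2 changes of the lines had r = 0.12. At 2-fold or more in both lines, 82 genes matched and 36 did not.

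**Figure D3:**
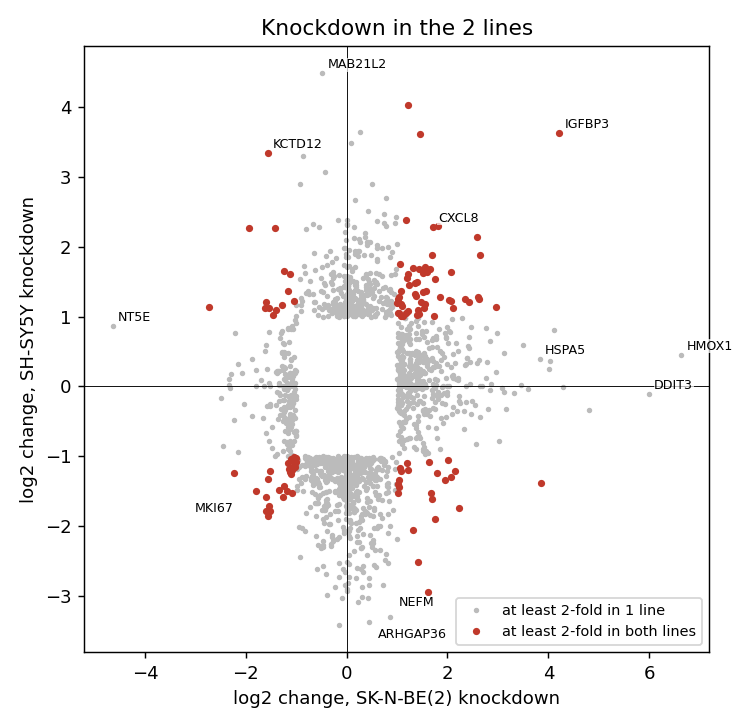
Log2 change by knockdown in SK-N-BE(2) (horizontal axis) and in SH-SY5Y (vertical axis), 1 point per gene changed at least 2-fold in at least 1 line, with red points for genes changed at least 2-fold in both. Of the red points, 82 changed the same way in both lines and 36 oppositely.

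The difference between the lines, the knockdown change in SK-N-BE(2) minus that in SH-SY5Y, was tested directly, with positive values for a higher change in SK-N-BE(2). HSPA5, NEFM and ARHGAP36 differed by 3.44, 4.15 and 3.82, and MAB21L2, KCTD12 and the cytoskeletal linker MSN by -4.97, -4.91 and -2.97 (limma adjusted p from 6.03e-20 to 2.73e-18). The neuronal list differed by a median of 2.04 (camera adjusted p = 2.56e-11), with 24 of 32 more positive and 3 more negative, and the ATF4 list by 1.87 (camera adjusted p = 4.63e-21), with 34 of 35 more positive and 0 more negative. The endoplasmic reticulum list differed by 2.04 (camera adjusted p = 3.4e-13, adjusted p = 0.054 with an estimated correlation), with 19 of 20 more positive and 1 more negative, and the hypoxia list by 1.12 (camera adjusted p = 2.56e-11), with 21 of 23 more positive and 0 more negative. Mitochondrially encoded subunits differed by -1.09 (camera adjusted p = 1.04e-08), with 0 of 13 more positive and 13 more negative, and NF-kappaB targets by -0.88 (camera adjusted p = 7.79e-07), with 0 of 13 more positive and 12 more negative. For immediate early genes the difference was 1.27 (camera adjusted p = 1.98e-10) and for heat shock proteins 0.87 (camera adjusted p = 8.74e-07). Calls lost with an estimated correlation were glycolysis (0.61), ferroptosis regulators (0.39), cholesterol synthesis (0.37), NRF2 genes (0.17), G1/S and S phase genes (0.30) and G2/M genes (0.32), with camera adjusted p from 4.52e-07 to 0.0346 and adjusted p of 0.121, 0.165, 0.263, 0.508, 0.53 and 0.508 with an estimated correlation. Adjusted over the list alone, these counts did not change. limma called 8873 genes (4687 more positive and 4186 more negative in SK-N-BE(2)), 1772 of them at 2-fold or more. The lines also differed in how far NDUFS6 fell, so the difference is not at an equal level of NDUFS6, and whether they carried the same hairpin is not given in the sources used here. With the other empty vector control of each line MSN was at -0.96. List medians there were -0.64 for mitochondrially encoded subunits, -1.58 for NF-kappaB targets, 0.68 for G1/S and S phase genes and 0.63 for G2/M genes. It ended the list calls of ferroptosis regulators (0.02), cholesterol synthesis (0.40) and NRF2 genes (0.18). Without SK-N-BE(2) knockdown replicate 2 the median was 0.11 for NRF2 genes and 0.18 for G1/S and S phase genes. Without SH-SY5Y knockdown replicate 2 the call was lost for NRF2 genes (0.15).

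Overexpression in SK-N-BE(2), where NDUFS6 RNA rose 1.34-fold, moved few genes by 2-fold. S100A6, a calcium-binding protein, rose from 0.641 ± 0.0208 to 13.5 ± 2.64 FPKM (log2 change 3.13, SE 0.189, limma adjusted p = 9.61e-10), and NDRG1, a hypoxia-induced gene, from 1.71 ± 0.428 to 6.68 ± 0.600 (log2 change 1.51, SE 0.0860, limma adjusted p = 5.06e-10). The other leading rises were 2.11 for LAMP5, 1.76 for TRAC, 1.65 for TWIST2, 1.52 for PP7080, 1.41 for AL445218.1 and 1.41 for C12orf29 (limma adjusted p from 1.95e-14 to 0.0138), and TRAC, the T cell receptor alpha constant region, was listed at 0 in the controls. The leading falls were -2.43 for RN7SL2, -1.39 for HIPK2, -1.32 for MIR4442, -1.32 for MBNL3, -1.3 for TXNIP, -1.3 for ZBED6, -1.20 for DLX1 and -1.19 for RNU6-720P (limma adjusted p from 3.01e-08 to 0.0281). RN7SL2, MIR4442 and RNU6-720P are small or structured RNAs whose values are uncertain in such libraries. The other control gave 1.20 for LAMP5, 1.05 for TRAC, 0.91 for AL445218.1 and 0.91 for C12orf29. There MIR4442 (-0.74) and RNU6-720P (-0.14) were not called and DLX1 (0.61) reversed. PP7080 (1.45 and 1.45) was not called without replicate 2 and control 3. RN7SL2 (-2.11, -1.62, -2.42 and -2.37) was not called without replicates 2 and 3 and controls 1 and 3. HIPK2 was -0.56 without replicate 2. MBNL3 (-0.66 and -1.23) was not called without replicate 3 and control 3.

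The hypoxia list was the only one called with both the preset and an estimated correlation: 14 of 23 rose and 0 fell (median 0.37, camera adjusted p = 2.32e-13), with BNIP3 and the collagen hydroxylase P4HA1 at 0.60 and 0.77. For glycolysis and glucose uptake 18 of 23 rose and 1 fell (median 0.29, camera adjusted p = 9.78e-14, adjusted p = 0.0586 with an estimated correlation), with the aldolase ALDOC at 0.90. Cytosolic ribosomal proteins were higher by a small amount: 64 of 68 rose and 0 fell (median 0.32, camera adjusted p = 3.26e-21, adjusted p = 0.437 with an estimated correlation), with RPL23A at 0.55. They held 7.56 ± 0.881% of the FPKM against 6.30 ± 0.370% in the controls, and 8.43% in overexpression replicate 2, which also had the fewest genes at 1 FPKM (12607) and the lowest slope of log2 level on gene length (-0.0332 per doubling). Of complexes II to V 18 of 38 rose and 0 fell (median 0.21, camera adjusted p = 4.88e-07, adjusted p = 0.586 with an estimated correlation), of the mitochondrial ribosomal proteins 14 of 50 rose and 1 fell (median 0.16, camera adjusted p = 1.99e-05, adjusted p = 0.568 with an estimated correlation), and of the nuclear complex I subunits 9 of 36 rose and 1 fell (median 0.14, camera adjusted p = 0.000429, adjusted p = 0.598 with an estimated correlation). In G2/M 22 of 37 rose and 2 fell (median 0.22, camera adjusted p = 1.1e-07, adjusted p = 0.139 with an estimated correlation). Against the other control, changes were 0.28 for BNIP3, 0.24 for P4HA1, 0.57 for ALDOC and 0.34 for RPL23A. List medians against it were 0.20 for cytosolic ribosomal proteins and 0.12 for complexes II to V. There complex I (0.15) lost its call and G2/M genes (-0.26) turned. Without overexpression replicate 1 the median was 0.24 for complex I, 0.32 for complexes II to V and 0.24 for mitochondrial ribosomal proteins. Without overexpression replicate 2 the median was 0.11 for complexes II to V, 0.07 for mitochondrial ribosomal proteins and 0.20 for cytosolic ribosomal proteins and the call was lost for complex I (0.08).

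Smaller shifts that rested on the preset correlation were called for cholesterol synthesis (2 of 21 rose, 10 fell, median -0.18), G1/S and S phase genes (3 of 31 rose, 11 fell, -0.07), MYC targets (9 of 32 rose, 3 fell, 0.10), immediate early genes (4 of 21 rose, 0 fell, 0.07), heat shock proteins (1 of 14 rose, 4 fell, -0.13), apoptosis regulators (3 of 26 rose, 10 fell, -0.06) and Schwann cell markers (3 of 5 rose, 1 fell, 0.27), with camera adjusted p from 0.00143 to 0.0313 and adjusted p of 0.139, 0.598, 0.598, 0.139, 0.437, 0.139 and 0.139 with an estimated correlation. Adjusted over the list alone, the counts were 21 and 0 for complexes II to V, 15 and 1 for mitochondrial ribosomal proteins, 68 and 0 for cytosolic ribosomal proteins, 20 and 1 for glycolysis, 15 and 0 for hypoxia genes and 10 and 3 for MYC targets, and unchanged elsewhere. The other control ended the calls of G1/S and S phase genes (-0.04), MYC targets (0.02), heat shock proteins (-0.15), apoptosis regulators (-0.01) and Schwann cell markers (0.06). The test of immediate early genes (0.02) turned there, uncalled. Without overexpression replicate 1 the median was 0.16 for MYC targets and the call was lost for G1/S and S phase genes, apoptosis regulators, immediate early genes, heat shock proteins and Schwann cell markers (-0.06, -0.01, 0.06, -0.13 and 0.26). Without overexpression control replicate 2 the call was lost for G1/S and S phase genes, apoptosis regulators, heat shock proteins and Schwann cell markers (-0.05, -0.03, -0.11 and 0.24). Without overexpression replicate 2 the call was lost for MYC targets (0.05).

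MYCN was at 1225 ± 58.3 against 924 ± 39.0 FPKM (0.41, limma adjusted p = 0.0135). ATF4, DDIT3 and CDKN1A changed by 0.26, 0.48 and -0.35 (limma adjusted p from 0.00814 to 0.0483). Markers of other cells gave 0.50 for PMP22, 0.90 for GFRA3, 0.35 for LUM, -0.89 for COL3A1, 0.16 for FBLN1, 0.15 for CD68, 0.12 for EPCAM, 0.06 for CLDN4, 0.42 for EGFL7 and -0.38 for EMCN, of which CD68, EPCAM, CLDN4 and EGFL7 did not pass the test (limma adjusted p from 0.0632 to 0.685). Log2 changes against the other control were 0.70 for ATF4, 1.37 for DDIT3, 0.92 for LUM, -1.47 for COL3A1 and -1.0 for EMCN. MYCN (0.15), PMP22 (0.04), FBLN1 (0.08), CDKN1A (0.11) and GFRA3 (-0.23) missed the call against the other control. MYCN (0.37), ATF4 (0.19) and LUM (0.31) were not called without replicate 2. CDKN1A (-0.37, -0.36, -0.33, -0.31 and -0.34) was not called without replicates 1, 2 and 3 and controls 1 and 3. FBLN1 (0.13, 0.15 and 0.14) was not called without replicates 2 and 3 and control 3. EGFL7 (0.52 and 0.55) was called without replicate 1 and control 3.

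limma called 4715 genes (29.7%), 2045 higher and 2670 lower, and 46 of them by at least 2-fold (28 higher, 18 lower). Of those 46, 18 (39.1%) were also at least 2-fold changed in the same direction against the other control. 29 (63.0%) were called in that direction at any size. Higher genes made up 43.4% of the calls and 32.7% under TPM scaling, 54.4% under median-of-ratios scaling and 54.8% with the length trend removed. Of the 46, 2 were at least 2-fold changed in the opposite direction against the other control. The count was 1186 with only the groups compared, 9374 with library weights, 2745 without overexpression replicate 2 and 3075 without overexpression control replicate 3.

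Overexpression in SH-SY5Y, with 19.0-fold more NDUFS6 RNA, moved few genes by 2-fold. CXCL8 rose from 1.35 ± 0.338 to 6.82 ± 0.348 FPKM (log2 change 1.75, SE 0.105, limma adjusted p = 5.04e-10), and UBTF from 13.3 ± 0.345 to 34.3 ± 1.04 (log2 change 1.31, SE 0.0492, limma adjusted p = 6.59e-13). TOMM6, of mitochondrial protein import, rose by 3.09 with an SE of 1.10 (limma adjusted p = 0.0367). The other leading rises were 2.14 for AC022336.2, 1.65 for PTX3, 1.6 for AC005828.4, 1.44 for IGFBP3 and 1.25 for Six3os1_1 (limma adjusted p from 7.39e-11 to 0.00534). The leading falls were -1.82 for AP001065.1, -1.76 for TSPEAR-AS1, -1.75 for TSPEAR-AS2, -1.37 for RAB6B, -1.34 for STON1, -1.3 for CACNA1G, -1.29 for ZCCHC24 and -1.27 for STMN4 (limma adjusted p from 6.59e-13 to 4.74e-09). Against the other control, log2 changes were 0.81 for CXCL8, 2.92 for AC005828.4, -2.17 for STON1, -2.04 for CACNA1G and -0.84 for STMN4. Against that control TOMM6 (1.16) and IGFBP3 (0.05) were not called. PTX3 (-0.43) reversed with the other control. TOMM6 (2.96, 3.25, 3.05, 2.95 and 2.50) was not called without replicates 1, 2 and 3 and controls 1 and 2.

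Of the inflammatory and NF-kappaB targets 10 of 13 rose and 0 fell (median 0.52, camera adjusted p = 9.1e-09), with the adhesion molecule ICAM1 and NFKB1 at 0.95 and 0.51. In the neuronal differentiation list 5 of 32 rose and 17 fell (median -0.18, camera adjusted p = 0.000366), with the microtubule protein MAPT and NEFL at -0.96 and -0.70. In the hypoxia list 1 of 23 rose and 14 fell (median -0.33, camera adjusted p = 1.27e-05), with BNIP3 and P4HA2 at -0.48 and -0.45. These were the 3 calls that also held with an estimated correlation. In G1/S and S phase 20 of 31 rose and 1 fell (median 0.27, camera adjusted p = 8.12e-09, adjusted p = 0.224 with an estimated correlation), and in the MYC and MYCN target list 19 of 32 rose and 2 fell (median 0.18, camera adjusted p = 2.02e-07, adjusted p = 0.249 with an estimated correlation). Of the p53 targets 2 of 27 rose and 15 fell (median -0.26, camera adjusted p = 0.000145, adjusted p = 0.104 with an estimated correlation), and CDKN1A went from 14.2 ± 1.75 to 7.69 ± 0.303 FPKM (-0.80, limma adjusted p = 9.5e-05). With the other control, values were -0.31 for NEFL, -0.93 for BNIP3, -1.37 for P4HA2 and -2.49 for CDKN1A. There ICAM1 (-0.73) reversed. The medians of lists there were -0.86 for hypoxia genes, 0.68 for G1/S and S phase genes, 0.47 for MYC targets and -0.93 for p53 targets. It ended the list calls of NF-kappaB targets (0.21) and neuronal differentiation (-0.03).

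Further calls that rested on the preset correlation were endoplasmic reticulum stress (11 of 20 rose, 0 fell, median 0.24), glycolysis (2 of 23 rose, 10 fell, -0.14), mitochondrial ribosomal proteins (12 of 50 rose, 0 fell, 0.12), mitochondrial folding stress (5 of 13 rose, 0 fell, 0.12), G2/M genes (13 of 37 rose, 1 fell, 0.10), immediate early genes (2 of 21 rose, 9 fell, -0.11), extracellular matrix (14 of 36 rose, 4 fell, 0.06), mitophagy (3 of 21 rose, 9 fell, -0.11) and cholesterol synthesis (8 of 21 rose, 5 fell, 0.15), with camera adjusted p from 0.000145 to 0.0242 and adjusted p of 0.359, 0.343, 0.567, 0.343, 0.5, 0.224, 0.343, 0.461 and 0.343 with an estimated correlation. The matrix gene TNC was at 0.79. Mitochondrially encoded genes held 28.3 ± 0.897% of the FPKM against 30.3 ± 0.347% in the controls. Adjusted over the list alone, the counts were 11 and 0 for mitochondrial ribosomal proteins, 6 and 0 for mitochondrial folding stress, 1 and 16 for hypoxia genes, 22 and 1 for G1/S and S phase genes, 22 and 2 for MYC targets, 2 and 16 for p53 targets, 5 and 19 for neuronal differentiation and 10 and 6 for cholesterol synthesis, and unchanged elsewhere. TNC (-1.44) reversed with the other control. List medians there were -0.38 for glycolysis, 0.23 for mitochondrial ribosomal proteins, 0.24 for mitochondrial folding stress and -0.36 for immediate early genes. List calls lost there were cholesterol synthesis (0.05). Tests turned there for extracellular matrix (-0.81) and, uncalled, G2/M genes (-0.03). Without overexpression replicate 3 the call was lost for cholesterol synthesis (0.08). Without overexpression control replicate 3 the median was 0.06 for G2/M genes.

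MYCN, ATF4 and DDIT3 gave log2 changes of 0.23, -0.16 and -0.04 and did not pass the test (limma adjusted p from 0.0819 to 0.856). Markers of other cells gave 0.05 for PMP22, 0.46 for GFRA3, -0.09 for LUM, 0.51 for COL3A1, -0.20 for FBLN1, -0.01 for CD68, -0.19 for EPCAM, -0.39 for CLDN4 and -0.40 for EGFL7, of which GFRA3, COL3A1, FBLN1 and CLDN4 passed the test (limma adjusted p from 1.19e-07 to 0.00519), while EMCN was listed at 0 in the controls. The other control gave 2.05 for GFRA3, -0.34 for FBLN1 and -0.87 for CLDN4. Reversed there was COL3A1 (-1.99). ATF4 (-0.23) was called without replicate 3. CLDN4 was -0.25 without replicate 3.

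limma called 5185 genes (32.6%), 2443 higher and 2742 lower, and 66 of them by at least 2-fold (21 higher, 45 lower). Of those 66, 37 (56.1%) were also at least 2-fold changed in the same direction against the other control. 43 (65.2%) were called in that direction at any size. Higher genes made up 47.1% of the calls and 54.9% under TPM scaling and 41.9% under median-of-ratios scaling. The count was 8809 against the other control.

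**Figure D4:**
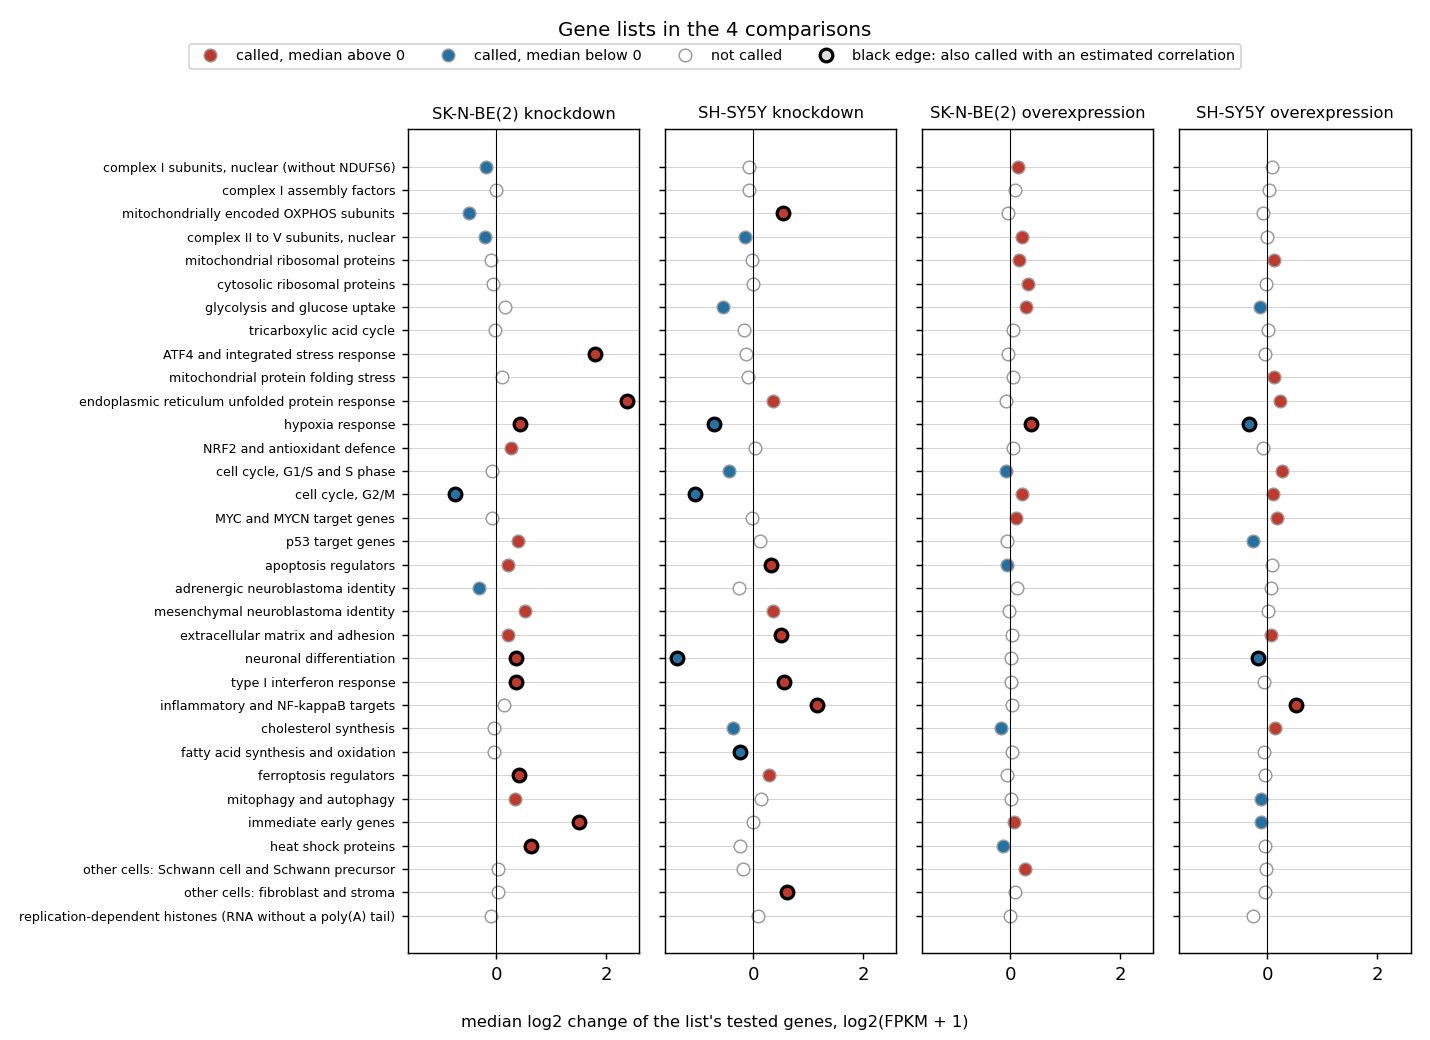
Median log2 change of the tested members of each of the 33 lists in the 4 comparisons, red or blue where camera called the list, white where it did not, with a black edge where the call held with an estimated correlation. The endoplasmic reticulum list stands at 2.38 in SK-N-BE(2) knockdown and the neuronal list at -1.39 in SH-SY5Y knockdown.

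Some genes changed the same way by overexpression in both lines. The chemokine CCL2, the hyaluronan receptor CD44, the G protein subunit GNG11, PRRT4, the hyaluronan synthase HAS2 and the receptor GFRA3 rose in both, by 0.73, 0.81, 0.49, 0.48, 0.63 and 0.90 in SK-N-BE(2) and 0.72, 0.57, 0.73, 0.86, 0.46 and 0.46 in SH-SY5Y. PDLIM3, AC234775.3, ATP1B3-AS1, L3MBTL3, the neuronal microtubule protein DCX and the BH3-only gene BMF fell in both, at -0.58, -0.58, -0.56, -0.53, -0.53 and -0.52 and -0.58, -0.59, -0.60, -0.53, -0.68 and -0.86. For SK-N-BE(2) overexpression, the other control gave 0.87 for GNG11, 1.55 for HAS2, -0.22 for PDLIM3 and -0.22 for L3MBTL3. AC234775.3 (-0.36), ATP1B3-AS1 (-0.36), CCL2 (-0.09) and CD44 (-0.25) were not called with the other control. PRRT4 (-0.17), DCX (0.47) and BMF (0.88) reversed with the other control. AC234775.3 (-0.39, -0.52, -0.61, -0.60 and -0.52) was not called without SK-N-BE(2) replicates 2 and 3 and controls 1, 2 and 3. ATP1B3-AS1 (-0.53 and -0.44) was not called without SK-N-BE(2) replicate 2 and control 2. For SH-SY5Y overexpression, the other control gave 0.19 for CCL2, 1.82 for GNG11, 1.98 for PRRT4 and -0.93 for ATP1B3-AS1. The other control left DCX (0.10) uncalled. There CD44 (-0.66) and HAS2 (-1.38) reversed. AC234775.3 (-0.57, -0.58, -0.61, -0.61 and -0.49) was not called without SH-SY5Y replicates 1, 2 and 3 and controls 1 and 2. 518 genes were called the same way (219 higher and 299 lower), fewer than the 314 and 460.4 that independent lists would share. Genes called in opposite directions numbered 1227, against 763 for independent lists, so that 29.7% of the genes called in both lines matched (Fisher's exact test p = 2.66e-67, two-sided, over genes). Across genes r was -0.16. At 2-fold or more in both lines 0 genes matched and 1 did not. The count was 841 without SK-N-BE(2) overexpression replicate 1 and 333 without SK-N-BE(2) overexpression replicate 2, 1604 against the other controls and 1465 with library weights.

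Tested directly, as the change in SK-N-BE(2) minus that in SH-SY5Y, the lines differed in the kinase gene CLK1, TRAC, the linker histone H1F0, COL3A1, UBTF and IGFBP3, by -1.61, 1.73, 1.52, -1.40, -1.43 and -2.19 (limma adjusted p from 8.53e-12 to 3.64e-11). Hypoxia genes differed by a median of 0.68 (camera adjusted p = 4.15e-12), with 18 of 23 more positive and 0 more negative, and the neuronal list by 0.20 (camera adjusted p = 0.000485), with 14 of 32 more positive and 3 more negative. Calls lost with an estimated correlation were glycolysis (0.53), cytosolic ribosomal proteins (0.35), complexes II to V (0.20), G1/S and S phase genes (-0.35), NF-kappaB targets (-0.57), endoplasmic reticulum stress (-0.29), immediate early genes (0.17), cholesterol synthesis (-0.28), apoptosis regulators (-0.26) and mitophagy (0.13), with camera adjusted p from 6e-11 to 0.0424 and adjusted p of 0.0773, 0.591, 0.684, 0.23, 0.148, 0.55, 0.0773, 0.148, 0.148 and 0.583 with an estimated correlation. Under TPM scaling the mitophagy list was at 0.06 (camera adjusted p = 0.0761). Adjusted over the list alone, the counts were 15 and 3 for neuronal differentiation, and unchanged elsewhere. limma called 5849 genes (2915 more positive and 2934 more negative in SK-N-BE(2)), 289 of them at 2-fold or more. Against the other control, changes were -0.65 for CLK1 and 1.02 for TRAC. Against it COL3A1 (0.52) and IGFBP3 (2.59) turned round. List medians against it were 1.20 for hypoxia genes, 0.33 for neuronal differentiation, -0.72 for G1/S and S phase genes and 0.64 for mitophagy. The other control ended the calls of complexes II to V (0.12), NF-kappaB targets (-0.28), endoplasmic reticulum stress (-0.25), immediate early genes (0.17), cholesterol synthesis (-0.10) and apoptosis regulators (-0.15). The call of complexes II to V was lost without SK-N-BE(2) overexpression replicate 2 (0.11). The median of complexes II to V was 0.32 without SK-N-BE(2) overexpression replicate 1. The call of apoptosis regulators was lost without SK-N-BE(2) overexpression replicate 1 (-0.25). The call of mitophagy was lost without SK-N-BE(2) overexpression replicates 2 and 3, SK-N-BE(2) overexpression control replicate 1 and SH-SY5Y overexpression replicate 3 (0.11, 0.08, 0.10 and 0.11).

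Knockdown and overexpression had separate control libraries, and genes that answered oppositely to them were counted per line. In SK-N-BE(2), DLX1, DLX2, GPR50, IGFBP3, AC093010.3 and COL3A1 rose in knockdown by 1.75, 2.68, 1.19, 4.21, 0.73 and 1.53 and changed in overexpression by -1.20, -0.97, -0.82, -0.75, -0.80 and -0.89. ITM2A, MT-TT, NT5E, hsa-mir-548d-1, CD44 and GFRA3 fell in knockdown (-2.34, -1.24, -4.64, -0.90, -1.62 and -1.15) and rose in overexpression (0.91, 0.89, 0.82, 0.82, 0.81 and 0.90). MT-TT and hsa-mir-548d-1 are small RNAs with uncertain values. For SK-N-BE(2) knockdown, the other control gave 1.03 for DLX2, 0.61 for GPR50 and -0.57 for CD44. Measured with the other control, AC093010.3 (0.29), DLX1 (-0.07), MT-TT (0.16) and hsa-mir-548d-1 (0.14) were not called. For SK-N-BE(2) overexpression, the other control gave -0.24 for GPR50. AC093010.3 (-0.37) and hsa-mir-548d-1 (-0.22) missed the call against the other control. Reversed there were DLX2 (0.68), IGFBP3 (2.64), ITM2A (-1.3), MT-TT (-0.51) and NT5E (-2.07). hsa-mir-548d-1 (0.65, 0.66 and 0.62) was not called without SK-N-BE(2) replicates 1 and 3 and control 2. 1482 genes of this line were called oppositely (782 higher and 700 lower in knockdown), where independent lists would share 732 and 578, and 1543 moved in the same direction under both, against 1315 (Fisher's exact test p = 0.632, two-sided; r across genes 0.03). At 2-fold or more under both, 1 gene was opposite and 7 moved alike. The count of opposite genes was 947 without SK-N-BE(2) overexpression replicate 2.

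In SH-SY5Y, ARL6IP5, EGR1, CD9, CAP2, SFRP1 and INSRR rose in knockdown by 1.07, 0.79, 1.20, 0.97, 1.41 and 0.79 and fell in overexpression, at -0.87, -0.84, -0.78, -0.77, -0.77 and -0.73. RGS7, SLC6A2, AC136621.1, FGL1, E2F8 and DRGX fell in knockdown (-1.19, -1.0, -0.73, -0.87, -0.66 and -0.65) and rose in overexpression (1.12, 0.73, 0.68, 0.68, 0.66 and 0.82). For SH-SY5Y knockdown, the other control gave 1.72 for EGR1, 2.13 for SFRP1, 1.31 for INSRR, -1.98 for SLC6A2, -1.86 for AC136621.1, -0.55 for FGL1 and -1.23 for DRGX. For SH-SY5Y overexpression, the other control gave -1.35 for ARL6IP5, -1.76 for EGR1, -1.36 for CD9, -1.49 for SFRP1, -1.25 for INSRR, 1.71 for SLC6A2, 1.81 for AC136621.1, 0.36 for FGL1 and 1.40 for DRGX. 1052 genes were called oppositely (509 higher and 543 lower in knockdown), against 722 and 724 for independent lists. More genes, 2611, moved in the same direction under knockdown and overexpression, against 1456 for independent lists (Fisher's exact test p = 2.12e-147, two-sided, over genes; r across genes 0.27). At 2-fold or more under both, 1 gene was opposite and 18 moved alike. With the controls exchanged, which adds the difference between them to the 2 comparisons with opposite signs, 3873 genes were opposite.

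The empty vector controls of a line, neither made to alter NDUFS6, differed from each other in many genes. In SK-N-BE(2), EGR1, NT5E, MSN and BCHE were higher in the knockdown control, by 3.07, 2.89, 2.46 and 2.28, and IGFBP3, MGP, FAM19A3 and IGHM lower, at -3.39, -2.10, -2.02 and -1.99 (limma adjusted p from 5.7e-19 to 9.57e-11). IGFBP3 stood at 1.04 ± 0.0391 FPKM in the knockdown control and at 20.4 ± 0.740 in the overexpression control. In SH-SY5Y, COL3A1, CYR61, C3 and MME were higher in the knockdown control, by 2.51, 2.45, 2.43 and 2.41, and RPL36A-HNRNPH2, INSM2, RN7SL2 and TFAP2B lower, at -4.22, -2.25, -2.07 and -1.92 (limma adjusted p from 3.7e-18 to 0.0495), with an SE of 1.14 for RPL36A-HNRNPH2. RN7SL2 (-1.54, -2.32, -2.36, -1.66 and -2.17) was not called without SH-SY5Y knockdown control replicates 1, 2 and 3 and SH-SY5Y overexpression control replicates 2 and 3. limma called 5487 genes between the controls of SK-N-BE(2) (2472 higher and 3015 lower in the knockdown control), 165 of them at 2-fold or more, and 5763 between those of SH-SY5Y (2926 higher and 2837 lower), 244 at 2-fold or more. At 2-fold these counts lay above the 46 and 66 of the overexpression comparisons and below the 724 and 1045 of the knockdowns.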

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

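Tests against the other empty vector control, with a length trend removed and of the ATF4 and endoplasmic reticulum lists in the second line were chosen after the files or the result had been seen. What singled out the following values was a tested difference between the lines, SK-N-BE(2) minus SH-SY5Y. By knockdown 8873 genes differed and by overexpression 5849, and NDUFS6 itself differed by -1.05 and -3.73. Under knockdown, ARHGAP36, NEFM and HSPA5 were more positive in SK-N-BE(2) (3.82, 4.15 and 3.44) and MAB21L2, KCTD12 and MSN more negative (-4.97, -4.91 and -2.97). Under overexpression, TRAC and H1F0 were more positive (1.73 and 1.52) and CLK1, COL3A1, UBTF and IGFBP3 more negative (-1.61, -1.40, -1.43 and -2.19). The median difference of the lists under knockdown was -1.09 for mitochondrially encoded subunits, 0.61 for glycolysis, 1.87 for ATF4 and integrated stress response, 2.04 for endoplasmic reticulum stress, 1.12 for hypoxia genes, 0.17 for NRF2 genes, 0.30 for G1/S and S phase genes, 0.32 for G2/M genes, 2.04 for neuronal differentiation, -0.88 for NF-kappaB targets, 0.37 for cholesterol synthesis, 0.39 for ferroptosis regulators, 1.27 for immediate early genes and 0.87 for heat shock proteins. Under overexpression it was 0.20 for complexes II to V, 0.35 for cytosolic ribosomal proteins, 0.53 for glycolysis, -0.29 for endoplasmic reticulum stress, 0.68 for hypoxia genes, -0.35 for G1/S and S phase genes, -0.26 for apoptosis regulators, 0.20 for neuronal differentiation, -0.57 for NF-kappaB targets, -0.28 for cholesterol synthesis, 0.13 for mitophagy and 0.17 for immediate early genes. Under knockdown, 7 of these 14 lists were not called with an estimated correlation, and 3 not against the other controls (NRF2 genes, cholesterol synthesis and ferroptosis regulators). Under overexpression, 10 of these 12 lists were not called with an estimated correlation, and 6 not against the other controls. COL3A1 and IGFBP3 reversed there.

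Stress genes of the endoplasmic reticulum and ATF4 lists were higher in SK-N-BE(2) knockdown. Control cultures that stood apart would have cost the endoplasmic reticulum list most of its median against the other empty vector control. Its median there was 2.10 (2.38 against its own). Scaling does not account for it either, with a median of 2.40 under median-of-ratios and 2.61 under TPM scaling. A response of any neuroblastoma line to loss of NDUFS6 stays open, since SH-SY5Y lost less (2.85-fold against 8.36-fold). In SH-SY5Y knockdown the ATF4 list was at -0.13 (1.8 in SK-N-BE(2)), though ATF4 itself rose. The endoplasmic reticulum list was at 0.36, not called with an estimated correlation (camera adjusted p = 0.355). The deeper knockdown, the line itself and an effect of the hairpin on other RNAs also stay open.

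Cytosolic ribosomal protein genes were higher in SK-N-BE(2) overexpression by a median of 0.32. With each library's length trend removed the median was 0.29, which argues against such a trend as the whole cause. Overexpression replicate 2 stood apart in several measures, and without it the median was 0.20, so that library is not the whole cause. These genes held 6.67, 8.43 and 7.59% of FPKM in replicates 1 to 3 and up to 6.71% in controls, so library differences stay open. With an estimated correlation the list was not called (camera adjusted p = 0.437). No biological explanation was tested, and NDUFS6 rose only 1.34-fold here.

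How far genes changed by knockdown depended on which empty vector culture they were set against. In SK-N-BE(2) 50.4% of the 724 genes passed 2-fold in the same direction against the other control and 91.9% were called in that direction at any size, so for most of the remainder only the size of the change is in question, and the parts of the control culture and of the hairpin in it cannot be told apart. In SH-SY5Y 79.6% of the 1045 genes passed 2-fold there, which argues against the control culture as the cause of most of them.

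Counts from relabelled libraries are the real value, the highest other split and the splits with at least the real value. For genes by knockdown they were 8854 and 1 in SK-N-BE(2) and 8899 and 0 in SH-SY5Y (1 of 10 each). By overexpression they were 4715 and 2908 in SK-N-BE(2) and 5185 and 2 in SH-SY5Y (1 of 10 each). For lists called, in the same order, they were 19 and 21 (4 of 10) and 17 and 18 (3 of 10) by knockdown. By overexpression they were 14 and 16 (2 of 10) and 15 and 14 (1 of 10). Between the empty vector controls they were 5487 and 0 in SK-N-BE(2) and 5763 and 2 in SH-SY5Y (1 of 10 each). 10 splits of 3 against 3 are too few for a share under 0.05. Other splits called as many lists except in SH-SY5Y overexpression, so list counts do not set the grouping apart. Between lines they were 8873 and 5458 for knockdown and 5849 and 4503 for overexpression (1 of 100 each). For opposite genes they were 1482 and 1543 in SK-N-BE(2) and 1052 and 2611 in SH-SY5Y (2 of 100 each). The higher split was the real grouping with 1 comparison turned round. For genes shared by both lines they were 3263 and 0 for knockdown and 518 and 0 for overexpression (1 of 100 each). Not drawn here, the turned split would give 2250 and 1227, and 1227 exceeds 518.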

How the results depend on the processing

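The other empty vector control, the length trend and protein-coding genes alone were alternatives chosen after the files had been seen. All 12 gene counts stayed within 1.5-fold with a pseudocount of 0.1, under TPM and median-of-ratios scaling, with the length trend removed, with protein-coding genes alone and with the replicate number as a block, where the counts of the 4 comparisons were 9136, 9173, 5179 and 5425. Libraries with the same number did not pair, with correlations of 0.14, 0.37 and -0.08 in SK-N-BE(2) overexpression and none over 0.1 elsewhere. The block ended 2 list calls, cholesterol synthesis in SH-SY5Y overexpression (camera adjusted p = 0.0513) and mitophagy and autophagy for overexpression between lines (camera adjusted p = 0.0515). A mean of at least 5 FPKM, which tests fewer genes, gave 4843 and 4592 genes for knockdown in SK-N-BE(2) and SH-SY5Y, 2885 for SH-SY5Y overexpression, 4573 and 3374 for the differences between lines by knockdown and overexpression, 1992 for the same way in both knockdowns, 3230 and 3207 between controls, and 9 lists called in SH-SY5Y overexpression. The 2-fold threshold, stricter by construction, left 724, 1045, 46 and 66 genes in the 4 comparisons, 1772 and 289 between lines, 82 and 0 shared between lines, 1 and 1 opposite, and 165 and 244 between controls. No filter, which adds low genes to the adjustment, left 335 genes changed the same way by overexpression. Library weights, whose estimation stopped before it converged, gave 9374 genes for SK-N-BE(2) overexpression, 8806 for overexpression between lines, 1465 for the same way by overexpression and 2978 for opposite genes in SK-N-BE(2), and the cause was not tested. Only the groups compared, with fewer libraries in the fit, left 1186 genes for SK-N-BE(2) overexpression and 870 opposite there. The other empty vector control gave 8809 genes for SH-SY5Y overexpression, 1604 for the same way by overexpression and 3873 for opposite genes in SH-SY5Y, and the cause was not tested. With an estimated correlation 9, 10, 1 and 3 lists were called in the 4 comparisons, in place of 19, 17, 14 and 15. NDUFS6 kept its call except in SK-N-BE(2) overexpression, where 0.39 had a limma adjusted p of 0.0511 with no filter and with only the groups compared.

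With 1 library left out at a time, where a group of 2 libraries shares the spread of the other groups, the counts ranged over 7987 to 8399, 8129 to 8232, 2745 to 6180 and 4223 to 4553 genes in the 4 comparisons, 8299 to 8641 and 5080 to 6748 between lines, 2989 to 3157 and 333 to 841 the same way, 947 to 1958 and 847 to 983 opposite, and 4579 to 4830 and 4751 to 5089 between controls. Lists called ranged over 19 to 21, 16 to 18, 10 to 15 and 14 to 16. NDUFS6 ranged over -2.49 to -2.30, -1.46 to -1.19, 0.33 to 0.49 and 4.08 to 4.16 in the 4 comparisons, -1.19 to -0.92 and -3.80 to -3.64 between lines and -0.26 to -0.08 and 0.01 to 0.09 between controls. Counts that moved more than 1.5-fold were 2745 for SK-N-BE(2) overexpression without its replicate 2 and 3075 without its control replicate 3, 841 and 333 for the same way by overexpression without SK-N-BE(2) overexpression replicates 1 and 2, and 947 for opposite genes in SK-N-BE(2) without overexpression replicate 2.

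Every called value that changed direction did so against the other empty vector control, and the cause was not tested. For lists, judged by the direction of the test, the median there was -0.26 for G2/M genes in SK-N-BE(2) overexpression, 0.020 for immediate early genes in SK-N-BE(2) overexpression, -0.0284 for G2/M genes in SH-SY5Y overexpression and -0.81 for extracellular matrix in SH-SY5Y overexpression. For genes, log2 changes were 0.0276 for MT-CYB, -0.0234 for ELAVL4, 0.19 for COL4A2, 0.24 for OAS3, 0.19 for PMP22, -0.16 for EPCAM, 0.0346 for EMCN, -0.0667 for DLX1, 0.16 for MT-TT and 0.14 for hsa-mir-548d-1 in SK-N-BE(2) knockdown. In SK-N-BE(2) overexpression they were 0.61 for DLX1, -0.0470 for ATP5O, -0.11 for ATP5G1, -0.11 for RPL13A, 0.28 for MCM6, 0.0671 for CCNE2, 0.0969 for MCM5, 0.20 for BUB3, -0.0838 for CCNB2, -0.17 for NUF2, -0.16 for FBL, 0.88 for BMF, 0.12 for HRK, 0.26 for SC5D, -1.95 for EGR1, -0.23 for GFRA3, 0.11 for CDKN1A, -0.0896 for CCL2, -0.25 for CD44, -0.17 for PRRT4, 0.47 for DCX, 0.68 for DLX2, 2.64 for IGFBP3, -1.30 for ITM2A, -0.51 for MT-TT, -2.07 for NT5E and -0.22 for hsa-mir-548d-1. In SH-SY5Y overexpression they were -0.43 for PTX3, -1.44 for TNC, -0.26 for THBS1, -1.99 for COL3A1, -0.73 for ICAM1, -0.66 for CD44, -1.38 for HAS2 and 0.10 for DCX. In overexpression between lines they were 0.52 for COL3A1 and 2.59 for IGFBP3. Of the 434 gene values set against that control, 337 kept direction and side of the threshold, 36 lost the call and 14 gained one, and of the 198 list values 135 did, with 25 lost and 34 gained. The 10 gained there with the largest medians were mesenchymal identity (-1.33), stroma markers (-1.27) and extracellular matrix (-1.22) for knockdown between lines, p53 targets (1.07), extracellular matrix (1.01), mesenchymal identity (0.87) and stroma markers (0.81) for overexpression between lines, stroma markers (-0.82) and mesenchymal identity (-0.73) in SH-SY5Y overexpression and p53 targets (0.78) in SH-SY5Y knockdown. Elsewhere list calls were lost for 59 of 198 values with an estimated correlation, 18 with protein-coding genes alone, 15 of 180 with a mean of at least 5 FPKM, 5 with library weights, 3 of 187 with only the groups compared, and 1, 1 and 1 with no filter, TPM scaling and the length trend removed. Gene calls were lost for 27 of 432 values with only the groups compared, 10 of 450 with no filter, 3 with a pseudocount of 0.1, 3 with the length trend removed, 1 of 324 with a mean of at least 5 FPKM and 2 and 3 under TPM and median-of-ratios scaling. With 1 library left out, 64 of 2745 gene values and 20 of 1572 list values lost their call. The unknown depth limits what can be said of genes near 1 FPKM.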
